A study of Mus musculus with 4 samples.

How the data were processed

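RNA profiles of bone marrow-derived macrophages from C57BL/6 mice aged 7 weeks were analysed after 24 h of IL-4. Each of 4 libraries came as a list of gene symbols with 1 value per gene. Total RNA was prepared with a kit for microRNA isolation and made into strand-specific libraries with the Agilent SureSelect kit, per the labels' protocols. The deposited values are FPKM, fragment numbers divided by transcript length and library size, that Cuffnorm 2.2.1 normalizes between libraries, per the submitters' processing notes. The same notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and the mouse genome build mm10. The gene annotation, the strand setting of the quantification and the treatment of reads that map to several places are not given in the sources used here. FPKM divides by gene length, so short features such as microRNA and snoRNA genes can take very large values from few fragments.

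Each file held 23284 symbols. 25 of these, all symbols that a spreadsheet reads as dates, had no value in any file, which left 23259. Positions were taken from the RefSeq annotation of GRCm38, the assembly that mm10 names, in which 23015 symbols were found. Exon lengths came from GENCODE. An exact 0 can be a failed estimate in these files: Gapdh, which macrophages express at a high level, was listed at 0 FPKM in 3 libraries and at 0.104 in the other. A gene at 0 is therefore described as listed at 0, with each library's value and without a fold.

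Depth was read from the low values. FPKM values under 0.1 of 1 gene in 2 libraries stood in whole-number ratios, within 0.02 on the log2 scale, in 87.6% to 91.8% of genes, against 17.8% for random ratios. Depth was estimated from these steps and GENCODE exon lengths. It came to about 9000000 and 9100000 fragments for the label wild type and 8200000 and 8500000 for the label Sema6D-/-. Cuffnorm had already normalized the values between libraries, and the annotation it used is not given. The number of fragments sequenced may therefore differ from these estimates. A single fragment on a transcript of 1 kb is then worth between 0.11 and 0.122 FPKM, and genes near 1 FPKM rest on few fragments.

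Groups follow the stated genotype of each sample. The sample titles start with K where the genotype label is wild type and with W where it is Sema6D-/-, which was not used for grouping. Every direction below is that of the genotype label, and an exchange of the labels would reverse each sign and leave each p-value as it is. No label says that the 2 libraries of a label come from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

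Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) on log2(FPKM + 1), for the 10115 genes with a mean of at least 1 FPKM over the 4 libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences on the log2(FPKM + 1) scale understate the change of genes with low values. Sema6d lies under the filter and was tested in a fit without it. The 32 gene lists were fixed before the data were examined and hold 678 entries, of which 673 were found, 18 under an older symbol. They cover the pathways of the series title, other macrophage programmes and markers of other cells that a marrow culture could hold. The 25 lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation of 0.01, two-sided and adjusted over the 25 lists. The alternatives were camera with an estimated correlation and fry, which asks another question, whether a list differs from no change. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries and not from the genes. With so few libraries, a call lost there does not show that correlation between members caused the loss.

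The genes named in the text were set by rule before the data were examined: Sema6d; the 12 largest higher and 12 largest lower differences among genes past the threshold whose libraries did not overlap between labels; up to 4 members per list by smallest p; and Pparg, Cd36, Arg1, Retnla, Chil3, Mrc1, Mtor, Abca1 and Srebf1. Names outside the rule are marked as chosen after their values were seen. The rule gave 140 genes, of which 1 is not reported here.

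The test was checked on simulated data for the same comparison of 10115 genes. Changed genes were drawn only from those at about 5 FPKM or more, and errors were independent and normal, from the fitted variances. Of 50 genes changed by each size, the test recovered 62% at a log2 change of 0.5, 92% at 1 and 100% at 2 and at 3. There were 13 false calls among 190. The check thus does not cover changes of genes nearer 1 FPKM or errors shared between genes. Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, eBayes without trend or with robust estimation, the title number as a block, leaving out each library, other gene list tests, and other thresholds. Leaving out small RNAs, and leaving out genes listed at 0 in any library, were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps.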

Results

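RNA was sequenced from macrophages that were grown from mouse bone marrow and then exposed for 24 h to IL-4, a cytokine that drives alternative activation. There were 2 libraries labelled wild type and 2 labelled Sema6D-/-, a genotype in which both copies of the gene for the membrane semaphorin Sema6D are disrupted. The FPKM values summed to 527755 and 538679 in the libraries labelled wild type and to 563890 and 552107 in those labelled Sema6D-/-. The estimated depth was about 8200000 to 9100000 fragments for each library. Over genes, Pearson's r of log2(FPKM + 1) was 0.9732 and 0.9693 between libraries of 1 label and 0.9545 to 0.9604 between labels, where genes are not independent replicates. Values below are mean FPKM ± SD with n = 2 libraries per label, and adjusted p-values are from limma unless a gene list is tested. Single libraries are named by their label and replicate number.

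The targeted gene was measured first. Sema6d, on chromosome 2 from 124089943 to 124667789 in mm10, was low in all 4 libraries, at 0.166 and 0.389 FPKM in those labelled wild type and 0.106 and 0.315 in those labelled Sema6D-/-. By the estimated depth, these values equal at most about 16, 37, 9 and 28 fragments. The difference of -0.08 ± 0.13 (SE) in log2(FPKM + 1) did not pass the test (adjusted p = 0.788), and it changed sign when wild type replicate 2 (0.05) or Sema6D-/- replicate 1 (0.05) was left out. The values thus do not separate the labels, and since gene-level FPKM do not show which exons were read, they do not check the genotype. The titles of the samples begin with K under the label wild type and with W under Sema6D-/-, so each direction below is given for the libraries as labelled.

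The comparison asks which genes, and which programmes of lipid metabolism, mTOR and PPARγ signalling, differ between the labels under IL-4. Interferon-stimulated genes and several inflammatory mediators were lower in the libraries labelled Sema6D-/-. C3, the central complement component, fell from 228 ± 7.9 to 29.4 ± 2.4 FPKM, and the chemokine gene Ccl5 from 108 ± 4.6 to 18.4 ± 0.94. Amino acid synthesis genes such as Asns, granulocyte genes such as S100a8, and the IL-4-induced genes Retnla and Chi3l3 were higher. The IL-4 response list went both ways, with 6 of 28 members higher and 6 lower. Of 10115 genes tested, 486 were higher and 497 lower at an adjusted p under 0.05, and 75 and 106 of them differed by at least 1 in log2(FPKM + 1). Leaving out 1 library lowered these counts to 256 higher and 290 lower (without wild type replicate 1), 276 and 260 (wild type replicate 2), 72 and 87 (Sema6D-/- replicate 1) or 112 and 164 (Sema6D-/- replicate 2). Groups did not overlap for 5687 genes, 56.22% against 33.3% by chance.

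**Figure D1:**
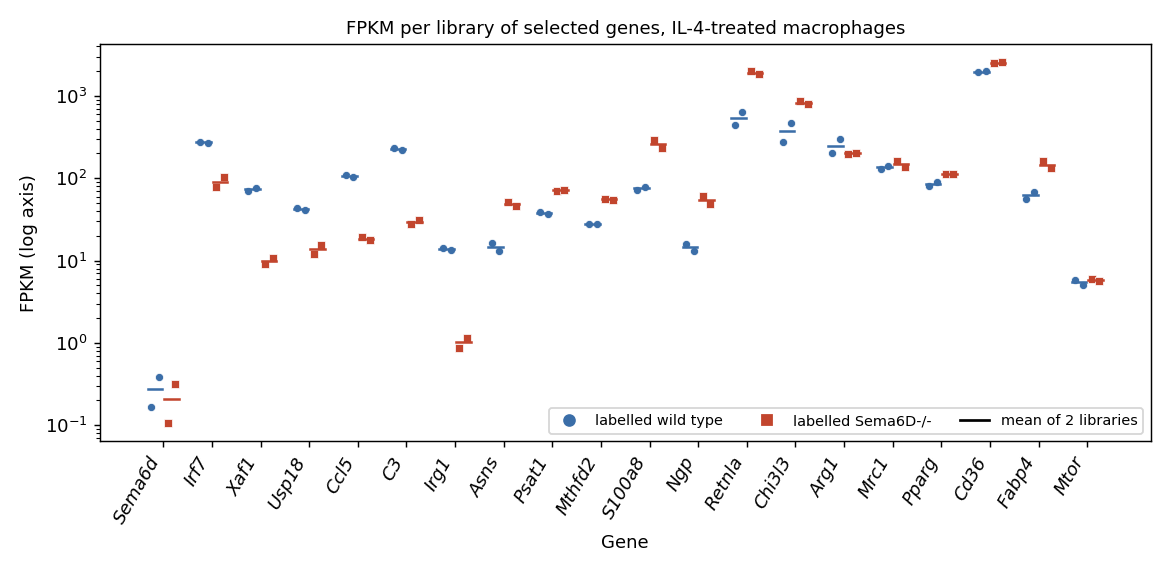
FPKM on a log axis of 20 genes in each library, with circles for libraries labelled wild type, squares for libraries labelled Sema6D-/- and bars for the mean of 2 libraries. Irf7 lies at 278 and 270 FPKM under the label wild type and at 77.5 and 102 under Sema6D-/-, while the values of Sema6d overlap.

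The 12 largest lower differences included immune genes. H2-M2, a class Ib histocompatibility gene, fell from 34.8 ± 8.7 to 1.46 ± 0.77 FPKM (adjusted p = 0.00208). Irg1, which makes the antimicrobial metabolite itaconate, fell from 13.9 ± 0.49 to 1.02 ± 0.20 (adjusted p = 0.00038). Xaf1 fell 7.48-fold, the C-type lectin gene Clec4n 10.7-fold, and the membrane protease gene Mmp14 13.3-fold. Prss37, Ly6i, Pira11, Ms4a4c and Clstn1 were lower by 62.4, 26, 16.6, 8.85 and 9.0-fold in mean FPKM. Rmrp was listed at 5.41 and 3.97 FPKM under the label wild type and at 0 in both libraries labelled Sema6D-/-. Ly6i, Pira11, Ms4a4c and H2-M2 belong to families with similar copies, so their levels are uncertain. Without Sema6D-/- replicate 1 or 2, Prss37 no longer passed (highest adjusted p = 0.0651).

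The 12 largest higher differences included several short or multi-copy features. Mir686 was listed at 0 in both libraries labelled wild type and at 4823 and 1996 FPKM in the others, and it overlaps Psmb5, a proteasome gene at 40.8 and 44.9 against 82.9 and 100.2 FPKM. Mir27a (1115 and 538 FPKM), Snord22 (35.3 and 34.0) and Snora52 (25.6 and 24.7) were also listed at 0 under the label wild type. Rpl3, a ribosomal protein gene with many pseudogenes, was at 0.474 ± 0.053 against 52.5 ± 0.59 FPKM. Reads shared with copies or overlapping genes leave these levels uncertain. Fblim1 on chromosome 4, which encodes a filamin-binding protein of cell adhesions, rose from 3.08 ± 0.47 to 66.1 ± 2.6 FPKM (adjusted p = 9.24e-05). Hmgn2, Gm13157 and C77080, also on chromosome 4, rose 33.8, 44.2 and 129-fold from means under 1 FPKM. Reads shared with similar copies were not excluded for these genes, so their folds are uncertain too. Nlrp1a, an inflammasome sensor, rose from 0.238 ± 0.034 to 4.17 ± 0.28, and Cox6a2 rose 10.6-fold.

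**Figure D2:**
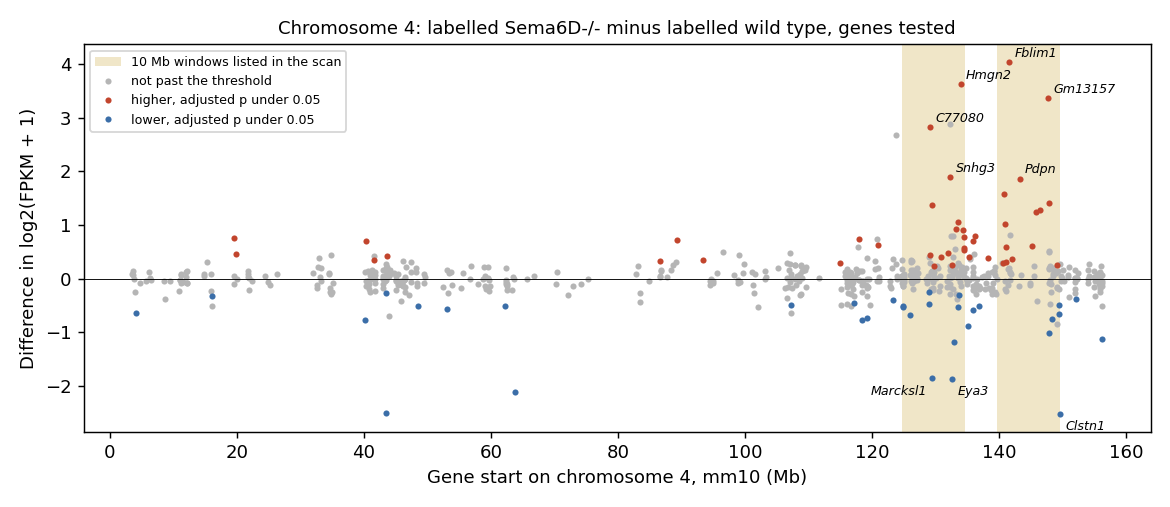
Difference in log2(FPKM + 1), labelled Sema6D-/- minus labelled wild type, of each tested gene by its start on chromosome 4 (mm10, Mb), with red and blue dots for genes past an adjusted p of 0.05 as higher or lower. Shaded 10 Mb windows hold 8 of 120 and 10 of 59 genes with a called difference of at least 1, among them Fblim1 at 4.04 and Clstn1 at -2.52.

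Interferon-stimulated genes formed the list with the smallest p. Of 27 members, 25 were lower in the libraries labelled Sema6D-/-, and Irf1 alone was higher (78.0 against 94.9 FPKM; named after its value was seen). Adjusted over the list alone, 26 were lower and 1 higher. Irf7, a transcription factor that amplifies the interferon response, fell from 274 ± 5.2 to 89.9 ± 18 FPKM and the deubiquitinase gene Usp18 from 42.0 ± 1.7 to 13.7 ± 2.2. Mx1, annotated as a transcribed pseudogene in the mm10 assembly, fell from 16.0 ± 0.52 to 5.51 ± 0.93. The list was lower by camera (median difference -0.90, adjusted p = 1.58e-18), a call lost with an estimated correlation (adjusted p = 0.512). It did not pass fry either (fry adjusted p = 0.056). Without Sema6D-/- replicate 1, 13 members were lower.

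Genes of inflammation and of antigen presentation were also lower. On the classical activation list 4 of 15 fell and Il10, an anti-inflammatory cytokine gene, rose from 0.36 ± 0.25 to 2.01 ± 0.30 FPKM. The 4 were Ccl5, Irg1, Ccl2 (43.8 ± 6.1 to 26.8 ± 0.81) and Ccl3, the last named after its value was seen. Adjusted over the list alone, 6 fell and 1 rose (camera adjusted p = 2.82e-04; adjusted p = 0.433 with an estimated correlation). Without Sema6D-/- replicate 1 or 2, only 2 of these members fell, and Il10 lost its call without either of them or wild type replicate 1 (highest adjusted p = 0.118). Of 8 class II presentation genes, 4 fell, with 5 lower when adjusted over the list alone. H2-Aa fell from 709 ± 36 to 480 ± 73 FPKM, H2-Ab1 from 470 ± 27 to 328 ± 32, H2-Eb1 from 202 ± 16 to 129 ± 17, and Cd74, the invariant chain, from 2764 ± 19 to 1946 ± 231. This list was lower by camera (adjusted p = 0.00819; adjusted p = 0.554 with an estimated correlation), with 0 members called without wild type replicate 2 or Sema6D-/- replicate 1. In the same libraries the dendritic cell marker Itgax fell and neutrophil markers were higher (list median difference 1.55).

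Genes of the amino acid response rose together. Of 23 targets of this response and of ATF4, the transcription factor that drives it, 16 were higher and Slc7a11, the cystine transporter gene, was lower (7.30 ± 0.11 against 4.19 ± 0.15 FPKM). Adjusted over the list alone, 18 were higher and 2 lower. Asns, asparagine synthetase, rose from 14.6 ± 2.2 to 49.0 ± 3.9 FPKM, Psat1 of serine synthesis from 38.0 ± 2.0 to 71.0 ± 2.1, Mthfd2 of mitochondrial folate metabolism from 27.5 ± 0.028 to 55.3 ± 0.50 and the transcription factor Atf5 from 49.2 ± 2.6 to 105 ± 4.3. The list was higher by camera (median difference 0.53, adjusted p = 7.46e-09; adjusted p = 0.433 with an estimated correlation). Fry, which tests a list against no change and not against the other genes, gave adjusted p = 0.00826. Neutrophil markers were higher in the same libraries too. Without Sema6D-/- replicate 1 or 2, 6 and 7 members were higher, and Slc7a11 lost its call without either of them or wild type replicate 2 (highest adjusted p = 0.1).

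Some genes of PPARγ and lipid uptake, which the series title names, were higher. Of 22 members 7 were higher and 2 lower, against 11 and 4 adjusted over the list alone. Pparg, the lipid-sensing nuclear receptor, rose from 84.7 ± 6.5 to 113 ± 0.27 FPKM (adjusted p = 0.0184), the fatty acid transporter Cd36 from 1971 ± 30 to 2539 ± 28 (adjusted p = 0.0128) and the fatty acid-binding protein gene Fabp4 from 61.9 ± 8.4 to 147 ± 20 (adjusted p = 0.00671). Msr1, a scavenger receptor gene, fell from 203 ± 14 to 157 ± 4.5. The list was higher by camera (median difference 0.22, adjusted p = 0.0194; adjusted p = 0.513 with an estimated correlation), and not without Sema6D-/- replicate 1 (adjusted p = 0.0551), without a filter (0.0736), with a mean of at least 5 FPKM (0.0639) or after quantile normalization (0.0528). Higher members numbered 3 without wild type replicate 1, 0 without Sema6D-/- replicate 1, 1 without Sema6D-/- replicate 2 or without a filter, and 2 with eBayes without trend. Neutrophil markers were higher in the same libraries (list median difference 1.55).

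Few mTOR pathway genes passed the test. Mtor itself was at 5.47 ± 0.54 and 5.83 ± 0.18 FPKM (difference 0.08 ± 0.10 (SE), adjusted p = 0.667). Of 30 components 2 were higher, Eif4ebp1, a translation repressor that mTOR phosphorylates (52.9 ± 0.94 to 67.5 ± 3.2), and the stress gene Sesn1 (26.2 ± 1.6 to 34.6 ± 1.0), and 4 were higher adjusted over the list alone. Pik3cd and Lamtor2 were at 31.5 against 38.1 and at 147 against 169 FPKM and did not pass. The list did not pass camera (adjusted p = 0.204). Eif4ebp1 lost its call without any 1 library (highest adjusted p = 0.119), and Sesn1 without wild type replicate 1 or either Sema6D-/- library (highest adjusted p = 0.173).

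Lysosomal genes and LXR targets showed a few changes each. Of 29 lysosome and TFEB targets 6 were higher and 0 lower, with 8 and 1 adjusted over the list alone. The protease genes Ctsd and Ctsl rose from 4366 ± 66 to 6809 ± 459 and from 1308 ± 137 to 1844 ± 108 FPKM, the autophagy receptor Sqstm1 from 353 ± 13 to 455 ± 6.3 and the proton pump gene Atp6v0d2 from 508 ± 31 to 701 ± 29. The list was higher by camera (adjusted p = 6.19e-04; adjusted p = 0.545 with an estimated correlation), with 3 members called without wild type replicate 1 and 0 without either Sema6D-/- library. Called members numbered 1 without a filter and 2 after quantile normalization or with eBayes without trend. Neutrophil markers were higher in the same libraries (list median difference 1.55). Among 10 LXR targets 3 were higher and 2 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.698). Apoe, a lipid carrier of secreted lipoproteins, rose from 3056 ± 441 to 5526 ± 440 FPKM and Nceh1 from 101 ± 4.3 to 121 ± 1.5, while the cholesterol exporter Abca1 fell from 20.5 ± 0.89 to 13.4 ± 0.70 and Arl4c from 61.9 ± 4.4 to 49.9 ± 0.14. After quantile normalization 0 were higher and 2 lower, without a filter 0 and 1, and with eBayes without trend 1 and 1. Without either Sema6D-/- library none of the 10 passed, with highest adjusted p-values of 0.129 for Apoe, 0.205 for Nceh1, 0.0833 for Abca1 and 0.217 for Arl4c.

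Few genes of lipid synthesis and energy metabolism passed the test. Of 14 fatty acid synthesis genes 1 was lower, Scd2, a desaturase (29.0 ± 3.2 to 16.3 ± 1.2 FPKM), also when adjusted over the list alone, and the regulator Srebf1 was at 20.8 ± 0.15 and 18.7 ± 0.16 (adjusted p = 0.185). That list was lower by camera (adjusted p = 0.0246; adjusted p = 0.512 with an estimated correlation). Of 22 cholesterol synthesis genes 1 was higher, Hmgcs1 (15.7 ± 1.2 to 20.6 ± 0.30), and 0 adjusted over the list alone (camera adjusted p = 0.783). Fatty acid oxidation had 2 higher, Hadhb (4.77 ± 0.28 to 7.98 ± 0.95) and Hsd17b4 (51.8 ± 0.21 to 61.9 ± 0.43), and 1 lower, the coactivator gene Ppargc1b (3.17 ± 0.28 to 1.65 ± 0.11), of 24, the same counts adjusted over the list alone (camera adjusted p = 0.182). Of 19 glycolysis genes 4 were lower, as adjusted over the list alone: the hexokinase genes Hk1 and Hk2, the aldolase gene Aldoc and the lactate exporter gene Slc16a3 (29.1 ± 1.5 to 20.3 ± 0.80), with camera adjusted p = 0.0364 (adjusted p = 0.62 with an estimated correlation). Gapdh and Eno1 lay under the filter and are not among the 19. Eno1 was listed at 0.80 and 0.79 FPKM under the label wild type and at 0 in both libraries labelled Sema6D-/-, where a 0 can be a failed estimate. Of 39 oxidative phosphorylation genes 2 were lower, Atp5d (192 ± 0.28 to 164 ± 0.17) and Cox7a2 (200.2 ± 4.6 to 172 ± 4.4), and 0 adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.433 with an estimated correlation). The list calls ended without wild type replicate 2 for fatty acid synthesis (adjusted p = 0.0515), without wild type replicate 1 (0.153) or Sema6D-/- replicate 1 (0.109) for glycolysis, and with a mean of at least 5 FPKM for both (0.169 and 0.0532). Hadhb, Hsd17b4, Ppargc1b, Hk1, Hk2, Atp5d and Cox7a2 lost their calls without any 1 library. Fewer libraries weaken the test, so a lost call need not mean a changed difference. Across these fits the difference ranged from -0.229 to -0.226 for Atp5d, from 0.246 to 0.26 for Hsd17b4 and from 0.528 to 0.743 for Hadhb. Scd2 (highest adjusted p = 0.0979), Slc16a3 (0.11) and Hmgcs1 (0.194) lost theirs without either Sema6D-/- library, Hmgcs1 also without wild type replicate 1, and Aldoc (0.0762) without Sema6D-/- replicate 1.

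Genes of the IL-4 response went both ways. Of 28 members 6 were higher and 6 lower (6 and 7 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.74), with a mean difference of 0.018, a median of -0.016 and a lower direction by camera. Retnla, a secreted marker of alternative activation, rose from 544 ± 143 to 1911 ± 105 FPKM, the chitinase-like gene Chi3l3 (now Chil3) from 371 ± 137 to 827 ± 44 and the ribonuclease gene Ear2 from 11.5 ± 1.4 to 27.3 ± 0.43. The chemokine gene Ccl22 fell from 28.4 ± 5.0 to 12.2 ± 2.8 and the arginine transporter gene Slc7a2 from 48.7 ± 3.8 to 29.9 ± 0.17. Arg1, arginase, was at 249 ± 67 and 202 ± 4.6 (adjusted p = 0.389) and the mannose receptor gene Mrc1 at 136 ± 6.6 and 150.1 ± 17 (adjusted p = 0.377). Without Sema6D-/- replicate 1 or 2, 1 member was higher each time and 0 and 2 were lower, and 2 were lower without wild type replicate 2. Without a filter 2 were higher and 1 lower, and with eBayes without trend 2 and 2. With 1 library left out, Retnla had highest adjusted p = 0.0742, Chi3l3 0.232, Ccl22 0.112 and Slc7a2 0.0726, while Ear2 passed in each case. S100a8, a neutrophil gene, was 3.49-fold higher in the same libraries.

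Markers of granulocytes were higher in the libraries labelled Sema6D-/-. Of 12 neutrophil markers 7 were higher and Csf3r, a growth factor receptor gene, lower (35.2 against 21.6 FPKM; named after its value was seen), with 10 and 1 adjusted over the list alone. S100a8 and S100a9, abundant calcium-binding proteins of neutrophils, rose from 75.6 ± 4.9 to 264 ± 44 and from 94.2 ± 6.5 to 316 ± 38 FPKM, the granule gene Ngp from 14.5 ± 1.9 to 55.2 ± 9.3 and Lcn2 from 6.26 ± 1.7 to 22.4 ± 0.095. The list was higher by camera (median difference 1.55, adjusted p = 3.63e-06). It did not pass camera with an estimated correlation (adjusted p = 0.513) or fry (fry adjusted p = 0.062). Every other list was compared in these same libraries. Of the eosinophil markers both tested genes were higher, Prg2 (0.947 ± 0.015 to 5.95 ± 2.9) and Ccr3 (3.99 ± 0.58 to 9.0 ± 0.39), as were 2 of 3 mast cell and basophil markers, Mcpt8 (0.238 ± 0.12 to 2.06 ± 0.052) and Prss34 (0.79 ± 0.15 to 5.02 ± 2.6), with the same counts adjusted over each list alone. Il6ra was at 9.96 and 11.6 FPKM. Leaving out 1 library ended the call of Ccr3 (either Sema6D-/- library), Prg2 (either wild type library), Mcpt8 (Sema6D-/- replicate 1) and Prss34 (all but Sema6D-/- replicate 2), with highest adjusted p-values of 0.0812, 0.0742, 0.0606 and 0.0971, and that of Lcn2 (either Sema6D-/- library, 0.0749).

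Macrophage and monocyte markers were mixed. Among 21 macrophage identity genes 4 were higher and 6 lower (5 and 9 adjusted over the list alone; camera adjusted p = 0.0664). The list passed as lower with a pseudocount of 5 (adjusted p = 0.037), without a filter (0.0377), after quantile normalization (0.0166) or without Sema6D-/- replicate 1 (0.0371). Emr1, which encodes F4/80, rose from 332 ± 9.3 to 470.2 ± 16 FPKM, whereas the endotoxin coreceptor Cd14 fell from 53.1 ± 2.5 to 27.8 ± 0.94, Csf2rb from 290 ± 11 to 180.2 ± 8.1 and Aif1 from 49.8 ± 0.38 to 33.3 ± 2.0. Of 7 monocyte markers 3 were higher and 3 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.74), among them Ly6c2 (0.756 ± 0.13 to 3.09 ± 0.18), Gsr (30.8 ± 1.2 to 41.2 ± 0.83), F13a1 (8.47 ± 0.39 to 2.98 ± 0.56) and Hp (3.36 ± 0.26 to 1.42 ± 0.098). Osteoclast markers gave 1 higher, Atp6v0d2, and 3 lower, Car2 (21.1 ± 3.6 to 6.6 ± 0.79), Mmp9 (23.6 ± 7.8 to 9.35 ± 0.81) and Dcstamp (95.9 ± 1.6 to 61.9 ± 7.0), of 10, with 1 and 4 adjusted over the list alone. That list did not pass camera (adjusted p = 0.464), with a median of 0.02 but a mean of -0.29. Among 5 dendritic cell markers Bst2 (460 ± 8.3 to 263 ± 10.5), also induced by interferon, and Itgax (404 ± 3.7 to 312 ± 11) fell, also adjusted over the list alone (camera adjusted p = 0.328), while Tcf4 and Ccr7 were at 8.29 and 8.79 and at 0.983 and 1.23 FPKM. Without Sema6D-/- replicate 1, macrophage identity genes gave 0 higher and 3 lower, and without Sema6D-/- replicate 2, 2 and 3. Monocyte markers gave 0 higher and 1 lower without either. Emr1 (highest adjusted p = 0.0646), Aif1 (0.0593) and Dcstamp (0.0523) lost their calls without Sema6D-/- replicate 1, and Ly6c2 (0.0558), Gsr (0.118), Hp (0.0998), Mmp9 (0.197) and Itgax (0.0974) without either Sema6D-/- library, Hp also without wild type replicate 2.

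Markers of other cell types were low or did not pass. None of 8 fibroblast markers passed (camera adjusted p = 0.246), with Acta2 at 2.14 ± 1.1 and 1.03 ± 0.026 FPKM, Col6a1 at 2.27 ± 2.0 and 1.03 ± 0.11, Dcn at 1.97 ± 0.72 and 1.35 ± 1.2 and Sparc at 4.16 ± 0.50 and 3.51 ± 0.057; without wild type replicate 1 the list was lower (mean difference -0.64, adjusted p = 3.15e-05). No B or plasma cell marker reached a mean of 1 FPKM. Of the other lists, the tested members Vwf (endothelial, 14.8 and 15.0 FPKM), Il7r (T and NK cells, 139 and 129), Pf4 and Beta-s (megakaryocyte and erythroid, 47.8 and 38.3, and 0.923 and 1.12) did not pass, over all genes or adjusted over the list alone. The Y-linked Ddx3y, Uty, Eif2s3y and Kdm5d were expressed in all 4 libraries and did not pass (adjusted p = 0.185 to 0.742).

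**Figure D3:**
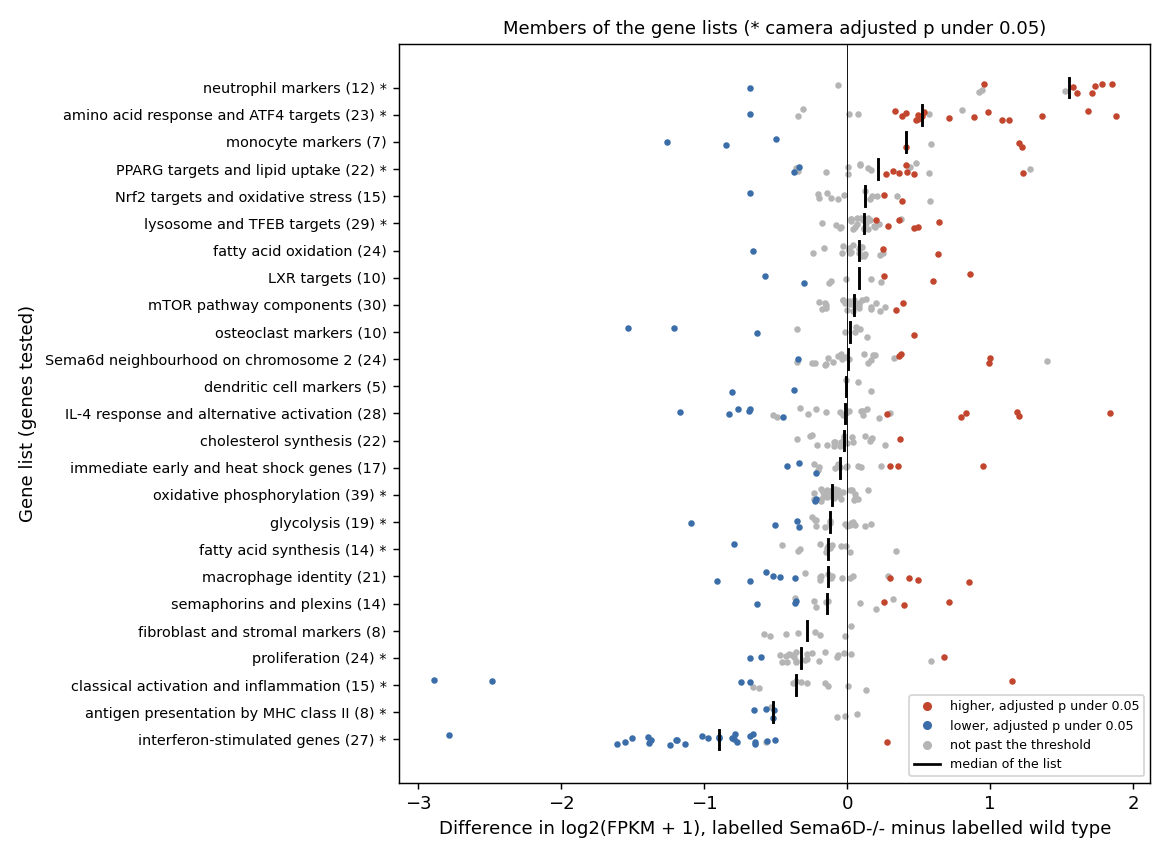
Difference in log2(FPKM + 1), labelled Sema6D-/- minus labelled wild type, of each member (dots) of the 25 lists tested, with the number of genes in brackets and the list median as a bar. Red and blue dots passed an adjusted p of 0.05 as higher or lower, an asterisk marks a camera adjusted p under 0.05, and the medians run from -0.90 for interferon-stimulated genes to 1.55 for neutrophil markers.

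Proliferation, stress and semaphorin lists complete the comparison. Among 24 proliferation genes Mki67 (2.24 ± 0.014 to 1.03 ± 0.042) and Birc5 (3.52 ± 0.062 to 1.98 ± 0.14) fell and Pcna, the DNA polymerase clamp, rose from 153 ± 5.8 to 244 ± 9.1 FPKM, with 3 lower and 2 higher adjusted over the list alone. The list was lower by camera (median difference -0.32, adjusted p = 5.97e-04; adjusted p = 0.512 with an estimated correlation), and not with a mean of at least 5 FPKM (adjusted p = 0.475). Of 17 immediate early and heat shock genes 3 were higher, including Egr1 (1.41 ± 0.0019 to 3.69 ± 0.87), Fos (37.5 ± 2.2 to 48.3 ± 2.1) and Zfp36 (83.5 ± 0.55 to 103 ± 1.2), and 3 lower, among them Hsph1 (61.1 ± 1.2 to 45.4 ± 1.0), with 3 and 6 adjusted over the list alone and camera adjusted p = 0.698 (mean 0.013, median -0.049). Of 15 Nrf2 targets Srxn1 (233 ± 5.7 to 305 ± 31) and Gstm1 (75.4 ± 1.4 to 90.2 ± 0.18) rose and Slc7a11 fell, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.591). Among 14 semaphorin, plexin and coreceptor genes 3 were higher and 3 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.478), including Trem2 (691 ± 53 to 1133 ± 23), Nrp1 (81.3 ± 7.9 to 107 ± 0.088), Plxna1 (112 ± 1.4 to 86.7 ± 0.021) and Sema4d (135 ± 0.40 to 106 ± 3.5). Near Sema6d on chromosome 2, 4 of 24 listed genes were higher, Spg11 (4.84 ± 0.059 to 10.6 ± 0.028), Slc30a4 (9.01 ± 0.028 to 19.1 ± 2.1), Eid1 (36.3 ± 0.11 to 47.0 ± 0.21) and Secisbp2l (19.9 ± 1.2 to 26.1 ± 0.81), and 1 lower, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.464, and fry adjusted p = 0.00826 against no change). Of these 4 only Slc30a4 passed whichever library was left out. Of the 107 named genes past the threshold in the libraries as labelled, 41 passed whichever library was left out. Mki67 and Birc5 lost their calls without any 1 library (highest adjusted p = 0.117 and 0.158). Egr1, Srxn1 and Gstm1 also lost their calls whichever library was left out. Every other called immediate early, heat shock or Nrf2 gene lost its call at least without either Sema6D-/- library. Of the semaphorin list 0 were higher and 0 lower without Sema6D-/- replicate 1, and 1 and 0 without Sema6D-/- replicate 2.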

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

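The alternatives were fixed before the data were examined, except those without small RNAs and without genes listed at 0. Each gene of the 983 called ones that an alternative fit tested kept its sign there. These genes were called for differences that were large against their spread in the same libraries, so their signs could hardly change. The counts of genes higher and lower, 486 and 497, became 256 and 248 without a filter (438 genes shared), 261 and 327 with eBayes without trend (555 shared), 300 and 337 with the replicate block, that is, with the title number as a paired term (618 shared), 789 and 759 at an adjusted p under 0.1, and 75 and 106 with a difference of at least 1. Leaving out 1 library, where the lone sample is assumed to vary like the other label's, gave 72 to 276 higher and 87 to 290 lower. Title numbers did not pair the samples (correlation of deviations across genes -0.018). Without small RNAs 589 and 587 passed, and without genes listed at 0, 588 and 590.

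Of the 11 gene lists past the threshold, 7 passed with a mean of at least 5 FPKM, where fewer genes were tested, and 0 with an estimated correlation. With fry, which tests against no change, 3 of them passed: amino acid response, classical activation and oxidative phosphorylation. Fry passed 4 lists in all, and the cause was not tested. Lists that fry did not pass included class II presentation (fry adjusted p = 0.12), PPARγ (0.0693) and lysosome (0.0693). The loss of all 11 calls with an estimated correlation does not show that correlated members made these calls. The amino acid list went from camera p = 5.97e-10 to p = 0.0271, although its estimated correlation of 0.015 was near the preset 0.01. For interferon-stimulated genes the estimate was 0.573. With 1 library left out, 9 to 11 of the 11 passed, and 10 to 11 lists in all. The mean of the IL-4 list, 0.018, came with a higher direction at a mean of at least 5 FPKM (0.069). With 1 library left out, the difference of Sema6d ranged from -0.204 to 0.049, Mtor from -0.005 to 0.166, Beta-s from -0.123 to 0.365, Col6a1 from -1.203 to 0.132, Dcn from -0.993 to 0.144, Eif2s3y from -0.051 to 0.187, Kdm5d from -0.021 to 0.141, Uty from -0.019 to 0.166 and Vwf from -0.003 to 0.041. The list means ranged from -0.064 to 0.101 for the IL-4 response, -0.054 to 0.025 for cholesterol synthesis, -0.643 to 0.072 for fibroblast markers and -0.034 to 0.06 for immediate early genes. None of these results passed with all 4 libraries. An estimated depth of about 8200000 to 9100000 fragments limits genes near 1 FPKM. For genes at about 5 FPKM or more, the simulation recovered 62% of log2 changes of 0.5.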

Other observations

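The genes in this paragraph were chosen after their values were seen. No list fixed in advance holds them as a group, and no enrichment was tested. In the libraries labelled Sema6D-/-, the MHC class I gene H2-K1 fell from 1792 ± 17 to 1277 ± 42 FPKM (SD, 2 libraries per label; limma adjusted p = 0.00644), H2-T24 5.3-fold and H2-Q7 3.77-fold, while B2m, the shared light chain gene, was at 7494 and 7464 FPKM and did not pass. The transporter gene Tap1 fell from 47.2 ± 2.2 to 29.1 ± 1.4 FPKM, and the immunoproteasome genes Psmb8 and Psmb9 from 255 ± 6.9 to 195 ± 4.2 and from 88.8 ± 1.4 to 62.6 ± 2.0. The secreted phosphoprotein gene Spp1 fell from 2000 ± 282 to 908 ± 23 FPKM and the endothelin gene Edn1 from 13.1 ± 1.6 to 1.74 ± 0.56. Ly6a, Slfn1 and Slfn4, which type I interferon induces, fell 5.07, 3.58 and 8.07-fold. The H2, Ly6 and Slfn genes have similar copies nearby, so their levels are uncertain.

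The tests below were chosen after the results were seen. For 2 tests on the distal chromosome 4 pattern, of genes outside shared families and of smaller differences, the prediction was written before the outcome. The pattern itself had already been found in these data. With 2 libraries per label only 3 splits of the 4 libraries into pairs exist, too few for a share under 0.05: the labels gave 983 genes and the higher of the other splits 5, and 1 split of the 3 reached the count of the labels.

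Interferon-stimulated genes were lower in both libraries labelled Sema6D-/-. Reads shared within tandem families do not account for this: 13 members lie outside the Ifit, Oas, Oasl, Gbp, Mx and Ifi20 families, 12 of them fell, and their median difference was -0.804. A single aberrant library does not account for it either, since the median of the list nearest to 0 with 1 library left out was -0.782. The genotype is a candidate explanation, and a difference between the cultures, the mice or their housing that follows the labels is another; neither was tested, because the labels record no day, animal or preparation.

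Neutrophil markers were higher in both libraries labelled Sema6D-/-, and no single library accounts for it (median difference nearest to 0 with 1 library left out, 1.193). RNA from neutrophil-lineage cells left in the culture is a candidate source, and should raise all markers by 1 ratio if no other cells express them. The 7 markers that passed rose 2.95 to 13.9-fold, with an SD of log2 ratios of 0.764 against a median of 1.046 in 10000 random sets of 7 from 99 genes that rose at least 2-fold, and 38.3% of the sets had as small an SD. These 7 were taken because they passed. Over all 12 listed genes the SD of log2 ratios was 1.111, with the granule gene Mmp8 at 25.96 ± 2.6 and 24.77 ± 0.60 FPKM (adjusted p = 0.687; named after its value was seen). Padi4, at 13.9-fold, and Csf3r, which fell, lie in the chromosome 4 region described below. Without these, chosen after their ratios were seen, the other 6 markers that passed rose 2.95 to 3.82-fold, with an SD of 0.138 against a median of 0.684 in 10000 random sets of 6 from 83 genes outside that region, and 0.93% of the sets had as small an SD. The wide spread of the 7 thus depends on Padi4, while the percentages of random sets also differ in the genes drawn from. Over all 10 listed genes outside the region the SD of log2 ratios was 0.618. The near-equal rise of the 6 goes with neutrophil RNA. But the 6 were taken because they passed, and a set chosen in this way does not decide between the sources. Of the 12 genes tested, 8 were at 1 FPKM or more under the label wild type, but the filter favours such genes among the 17 listed. Those under it were low but higher in both libraries labelled Sema6D-/-. Ctsg was at 0 and 0.37 against 2.36 and 0.94 FPKM, Prtn3 at 0 and 0.26 against 0.58 and 2.09, and Fcnb at 0 and 0 against 0.26 and 0.62. Chi3l1 was at 0.34 and 0.20 against 1.86 and 1.58, and Cxcr2 at 0.53 and 0.24 against 0.74 and 0.75. Mmp8 outside the region did not pass. Such cells and a change of expression within the macrophages thus cannot be told apart.

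Large differences of both signs gathered on distal chromosome 4. In a scan of 10 Mb windows over 10039 placed genes, 174 of them with a called difference of at least 1, the window from 139622871 to 149622871 (mm10) held 10 such genes among 59 (permutation p = 0.008 over all windows, 2000 permutations), so chance placement is argued against; the window from 124657646 to 134657646 held 8 of 120 (permutation p = 0.1019). A chromosome segment of other strain origin in the mice of 1 label is a candidate explanation: among genes with smaller differences between 124657646 and 149622871, 15.79% were called against 7.89% elsewhere (one-sided Fisher's exact p = 0.000134), a region set by the scan itself. Reads shared between paralogs or pseudogenes remain open too. Without predicted genes, pseudogenes and shared symbol stems, 4 of 47 genes in the leading window differed by at least 1, 8.51% against 1.64% elsewhere. The prediction for shared reads was a count that random reassignments often reach, and that prediction was met (permutation p = 1). But the test set the count against the highest window of each permutation, which any low count falls under, so it decides nothing. The window was itself chosen for its count. Sema6d lies on another chromosome, and an effect of its genotype on these genes was not tested.

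Around Sema6d on chromosome 2, 20.8% of the 24 listed genes were called against 9.68% of the others, which did not pass (one-sided Fisher's exact p = 0.0767). Whether a segment of other strain origin may surround the targeted gene stays open with so few genes. Eya3 fell from 81.4 ± 0.94 to 21.6 ± 0.061 FPKM, Marcksl1 fell 4.59-fold and Hdac1 rose 3.65-fold within the chromosome 4 region, and Plod1 rose from 12 ± 0.33 to 33.7 ± 1.3; these genes were named after their values were seen. In other windows of the scan, 9 of 136 genes differed by at least 1 on chromosome 15 from 72589620 to 82589620 (permutation p = 0.0275) and 8 of 175, all lower, on chromosome 17 from 26123503 to 36123503 (permutation p = 0.1019). Those on chromosome 15 included Ly6i, Ly6a, Ly6c2 and Rpl3, and those on chromosome 17 H2-Q6, H2-Q7, H2-T24 and H2-T10. These genes have similar copies, and the permutations placed each gene singly, so neighbours that change together can raise such counts.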
